A study of Mus musculus with 8 samples.

How the data were processed

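Single-cell RNA libraries of CD8+ T cells from C57BL/6 mice were made with the Chromium Single Cell 3′ v2 kit, per the labels. The deposited data cover 8 samples that form 6 libraries, because the 2 technical runs of OVA-specific WT replicate 2 and of OVA-specific KO replicate 1 were combined by the authors. The deposited values are raw UMI counts per gene and barcode, made by the authors with Cell Ranger on mm10 per the submitters' processing notes. The Cell Ranger version and the rule by which barcodes were called cells are not given in the sources used here. Groups were taken from the labels: naive WT (1 library), naive KO (1), OVA-specific WT (2) and OVA-specific KO (2).

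Nearly every barcode was listed with suffix 1 and again with suffix 2. At least 99.0% of the distinct barcodes of each library occurred with both suffixes, and the median pair shared 80.7% to 86.9% of its detected genes, against 19.0% to 27.7% for random pairs. The entries with suffix 1 were used as the cells, and those with suffix 2, and the sum of both, as alternatives.

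Of 5013 barcodes, those with fewer than 400 detected genes (213) or more than 10% mitochondrial UMIs (43) were left out. Doublets were then removed in each library at an expected rate of 0.8% per 1000 barcodes (40 cells, scores from Scrublet as built into scanpy), which left 4747 cells. No cluster was named for another cell type, so no cell was left out on that ground. The libraries held 1302549 to 5093322 UMIs after filtering. Cells were scaled to 10000 UMIs, reduced to 2000 variable genes and 20 principal components, and clustered with the Leiden method at resolution 1.0 on a graph of 15 neighbours (seed 1). A cluster was named from marker lists only where at least 3 markers were raised in it, except that a cluster under 0.5 of its libraries' median depth with none of those markers among its 10 leading genes stayed unnamed (1 cluster, at 0.365). That limit was set after the clusters were seen, and a limit of 0.333 would have named this cluster cycling. Markers of another class were not to outnumber its own there. Classes were compared only over clusters whose 10 leading genes held no gene called between the genotypes over all OVA-specific cells. Depth per cell limits shares of cells, so every cell was thinned to 2000 UMIs and shallower cells were left out of those shares. Intervals are exact Poisson for counts, exact conditional for ratios and exact Clopper-Pearson for shares, at 95%.

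UMIs were summed over the kept cells of each library. Genes passing filterByExpr were tested with the edgeR quasi-likelihood test after TMM scaling, two-sided, with Benjamini-Hochberg adjustment at 0.05. KO was compared with WT in the 4 OVA-specific libraries (2 residual degrees of freedom). OVA-specific cells were compared with naive cells with genotype as a term, and the interaction of genotype and infection was tested over all 6 libraries. The genotype comparison was repeated on summed cycling cells, the only named class with 50 or more cells in every OVA-specific library. The naive pair has no replicates and got a size rule of 50 UMIs in the higher library and 1.5-fold, with no test. Shares of cells were compared with an exact permutation test over libraries, which cannot give a p under 0.33. A gene without UMIs in a group got a fold against a floor of 3 UMIs over that group.

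Of 31 gene lists fixed beforehand, 2 (receptor and immunoglobulin segments) held no gene of the files, and the gamma-delta marker list had 0 tested genes. Lists with 5 or more tested genes were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. In the naive pair, list medians were set against 10000 random lists matched on expression in 20 bins. Named genes were, in the 2 main comparisons, up to 12 per direction by log2 fold change among called genes with a mean of at least 20 CPM in the higher group and no overlap between the groups' libraries, receptor segments left out. In the naive pair they were the 10 highest and 10 lowest ratios, and in the interaction and the cycling cells the 5 genes per direction with the smallest p. Suv39h1, the panel genes of the shares and up to 4 members per list by smallest p (in the naive pair by UMI count) were added. The remaining genes called between genotypes in OVA-specific cells, the paralogs AC168977.1, Lilrb4a and Ly6c1, and the sixth interaction gene below 0 were named after their values were seen. Not every gene that the rule picks is printed.

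The comparisons, filters, lists, naming markers and most alternatives were set before the data were examined. The alternatives were RLE size factors, DESeq2 in place of edgeR, no low-count filter, no cell filter, a stricter filter (800 genes, 5% mitochondrial), doublets kept, each library left out, the replicate number as a block, all 6 libraries in 1 fit, cycling clusters left out, 279 cells per library, thinning to 1302549 UMIs, 1 genotype at a time, other thinning depths (1000 and 3000 UMIs) and other Leiden resolutions (0.5 and 1.5). Suffix 2, both suffixes summed, the low-UMI cluster left out or counted as cycling and the terminal-effector-like cluster left out were chosen after seeing the data. Keeping clusters of other cell types coincided with the main setting. The tests were tested on simulated data in 10 runs with 200 changed genes: with 2 libraries per group 13.5%, 53.3% and 93.2% of 1.5-fold, 2-fold and 4-fold changes were recovered with 4.68% false calls, and for the interaction 0.882%, 7.73% and 51.8% with 6.12% false calls. For OVA-specific against naive cells the shares were 17.1%, 56.8% and 91.1% (4.96% false) and within cycling cells 13.4%, 49.1% and 90.9% (5.49% false). In such data camera called a shifted list in 10 of 10 runs with 0 other lists called. Simulated genes were drawn independently, with a spread set by their expression level alone. The runs therefore cannot show how often camera calls a list falsely where genes move together, nor cover genes of unusual spread.

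Positions came from the GENCODE annotation of mm10, which matched 27645 of 27998 genes. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.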

Results

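CD8+ T cells of C57BL/6 mice were profiled by droplet single-cell RNA sequencing in wild-type (WT) animals and in animals lacking Suv39h1 (KO). Naive cells gave 1 WT and 1 KO library. Kb-OVA-positive cells, sorted on day 7 after infection with Listeria monocytogenes expressing OVA and called OVA-specific here, gave 2 WT and 2 KO libraries. The kept cells numbered 936 in naive WT, 930 in naive KO, 402 and 1233 in OVA-specific WT replicates 1 and 2, and 967 and 279 in OVA-specific KO replicates 1 and 2. Their UMIs (counted transcript molecules) summed to 1790050, 2322606, 1513598, 5093322, 4701674 and 1302549 in the same order. The median cell held 1929.5 UMIs in naive WT and 2465 in naive KO, against 3359, 3942, 4492 and 4371 in the OVA-specific libraries. The labels call the replicates biological without saying that they came from separate mice, so p-values measure the spread between these libraries, which may be technical. Intervals on UMIs and on shares of cells cover counting error only.

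Suv39h1, which encodes a histone H3 lysine 9 methyltransferase, was detected in every WT library and in none of the KO libraries. The gene (ENSMUSG00000039231) lies on chromosome X from 8061171 to 8074760 on the minus strand of mm10. It had 21 UMIs in naive WT cells, or 11.7 CPM (UMIs scaled to a common library total; exact Poisson 95% interval 7.26 to 17.9), and 27 and 74 UMIs in the OVA-specific WT replicates, or 17.8 and 14.5 CPM. The KO libraries had 0 UMIs; a floor of 3 UMIs corresponds to 1.29 CPM in naive KO and to 0.638 and 2.30 CPM in the OVA-specific KO replicates. In OVA-specific cells Suv39h1 was at least 30.6-fold lower in KO, against a floor of 3 UMIs over the group (edgeR adjusted p = 0.0011). The labels do not give the deleted part, and a 3′ tag outside it would check nothing, but the tags that were absent here separated the genotypes as labelled.

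OVA-specific KO cells were compared with OVA-specific WT cells to ask which transcripts depend on Suv39h1 on day 7 of the response. Of 8730 genes tested, 31 changed, 14 higher and 17 lower in KO (edgeR quasi-likelihood test, n = 2 libraries per genotype). Il7r, the interleukin 7 receptor chain that supports survival of naive and memory T cells, rose 3.40-fold, from 22.5 and 28.5 CPM in WT to 95.9 and 67.6 CPM in KO (log2 fold change 1.76, SE 0.22, adjusted p = 0.0058). Lag3, an inhibitory receptor, rose 34.6-fold, from 0 and 0.785 CPM to 21.5 and 19.96 CPM (adjusted p = 0.000885). The size of the Lag3 change rests on 4 UMIs in WT replicate 2, and its log2 value of 5.11 ranged from 4.44 to 8.76 over the alternatives. S1pr5, a sphingosine 1-phosphate receptor of effector T and NK cells, fell by 1.88 on the log2 scale (SE 0.19, adjusted p = 0.0011), from 99.8 and 77.6 CPM to 22.97 and 19.96 CPM. Zeb2, a transcription factor of terminal effector differentiation, fell by 1.05 (SE 0.16, adjusted p = 0.0227), from 277 and 203 CPM to 96.6 and 118 CPM.

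Among the other genes higher in KO, AC168977.2, an unplaced scaffold's gene, went from 0 UMIs in WT to 28.3 and 16.9 CPM, at least 56.9-fold against a floor of 3 UMIs over the group. Lilr4b, an immunoglobulin-like receptor, rose 5.04-fold. Its value is uncertain because its paralog Lilrb4a, which did not pass (adjusted p = 0.0546), may share its reads, as AC168977.1 may share those of AC168977.2. AA467197 rose 2.82-fold, Fcgrt (the neonatal Fc receptor) 2.26-fold, Anxa1 (annexin A1) 2.12-fold, Bin1 2.04-fold, Cirbp (a cold-inducible RNA-binding protein) 1.84-fold, Il18r1 (an interleukin 18 receptor chain) 1.83-fold and 1500009L16Rik 1.69-fold. The 3 called genes below 20 CPM in both genotypes, C130026I21Rik, P2ry14 (a UDP-sugar receptor) and Flywch1, rose 13.6-fold, 4.99-fold and 7.57-fold. The log2 value of C130026I21Rik, 3.77, became 7.97 without WT replicate 2, and that of Flywch1, 2.92, became 3.65 there and lost its call (adjusted p = 0.0692). The calls of Flywch1 (adjusted p = 0.0535) and P2ry14 (0.0519) also ended without WT replicate 1, and that of C130026I21Rik without KO replicate 1 (0.0661).

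Ly6c2, which encodes the surface protein Ly6C of effector and memory cells, was the most abundant gene to fall: 2400.2 and 2200.5 CPM in WT against 883.9 and 935.9 CPM in KO, a 2.33-fold reduction (SE of the log2 value 0.13, adjusted p = 0.0011). Its value is uncertain because its close relative Ly6c1 may share reads with it. Prkcz, an atypical protein kinase C, was 11.2-fold lower and Fkbp10 5.48-fold lower, both below 20 CPM. The log2 value of Fkbp10, -2.46, became -1.52 without KO replicate 1 and lost its call (adjusted p = 0.149), and Prkcz lost its call without WT replicate 2 (adjusted p = 0.0709). Tmem37, Ppp1cc (a protein phosphatase 1 subunit), Tesc, Xpa (a DNA excision repair factor), Cd68 (a lysosomal glycoprotein), As3mt and Tprgl were 2.46-fold to 3.39-fold lower. Polr2m, Vapa, Chd3 (a chromatin remodeller) and Rap1b (a small GTPase) were 1.77-fold to 2.23-fold lower. AA467197, AC168977.2, Anxa1, Il7r, Lag3, Lilr4b, Ly6c2 and S1pr5 were called in each of 18 alternative settings. The count of 31 was 209 without WT replicate 2 (168 higher and 41 lower), 301 without KO replicate 1 (75 and 226) and 101 without KO replicate 2 (41 and 60), with the lone library assumed to vary like the others. The balance of directions thus turned with the library left out. Of the 31 genes, 23 were still called without WT replicate 1, 26 without WT replicate 2, 28 without KO replicate 1 and 29 without KO replicate 2. Calls that ended, beside those given above, were those of Bin1, Cirbp, Tesc, As3mt, Polr2m and Chd3 without WT replicate 1, Tmem37, Ppp1cc and Xpa without WT replicate 2, and 1500009L16Rik and Rap1b without KO replicate 2, while Flywch1 was not tested without KO replicate 1. DESeq2 called 21 genes, 17 of them among the 31; among the calls it ended were those of Prkcz (adjusted p = 0.126), Cirbp (0.127), Cd68 (0.161), P2ry14 (0.161), Chd3 (0.223), Fkbp10 (0.327) and Flywch1 (0.568). The count of 31 was 185 without the low-count filter, 16 with equal numbers of cells per library and, in a setting chosen after seeing the data, 20 without the cluster of terminal-effector-like cells. In that last setting Zeb2 stood at -0.908 on the log2 scale and lost its call (edgeR adjusted p = 0.0703).

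**Figure D1:**
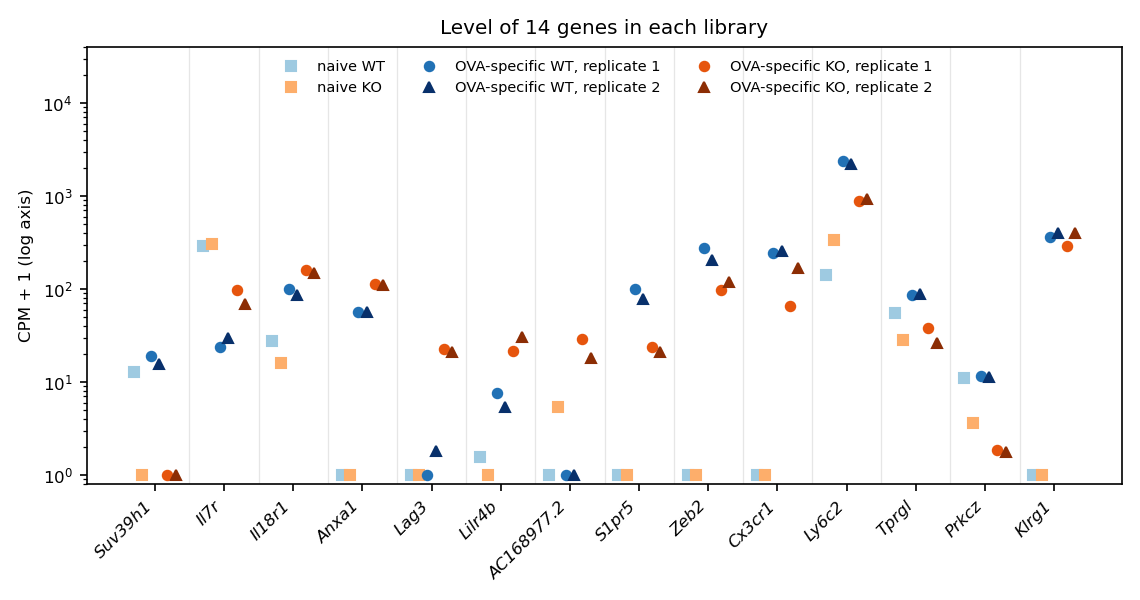
CPM + 1 (log axis) of 14 genes in each of the 6 libraries: squares are naive, circles and triangles are OVA-specific replicates 1 and 2, blue is WT and orange KO. Il7r stood at 95.9 and 67.6 CPM in OVA-specific KO against 22.5 and 28.5 CPM in WT, and S1pr5 at 22.97 and 19.96 CPM against 99.8 and 77.6 CPM; Cx3cr1 and Klrg1 did not pass the test.

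Several markers of effector and memory cells did not pass the test. Cx3cr1, a chemokine receptor of effector cells, had 244 and 253 CPM in WT and 65.1 and 167 CPM in KO (log2 fold change -1.08, adjusted p = 0.766), and passed only without KO replicate 2 (-1.83, adjusted p = 4.28e-12). Klrg1, an inhibitory lectin receptor of terminal effectors, stood at 362 and 396 CPM in WT and 289 and 401 CPM in KO (adjusted p = 0.982). Its log2 fold change of -0.04 (SE 0.17) turned to 0.12 without WT replicate 2 and to 0.20 without KO replicate 1. Gzmb, the granzyme B gene, had a log2 fold change of 0.66 (adjusted p = 0.192), S1pr1 of 0.70 (adjusted p = 0.237), Cxcr3 of 0.48 (adjusted p = 0.22) and Eomes of -0.93 (adjusted p = 0.12). Without the low-count filter Gzmb, S1pr1 and Eomes passed (adjusted p = 0.00222, 0.00331 and 0.00343). So did Gzmb and S1pr1 without KO replicate 1 (0.0498 and 0.0126), S1pr1 without WT replicate 2 (0.00435) and Eomes without KO replicate 2 (0.00958).

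Of 24 lists of genes fixed beforehand and tested with camera, 6 moved against the other genes between KO and WT OVA-specific cells, and none of the 6 calls held with an estimated correlation. All 81 ribosomal protein genes lay above 0 (median log2 fold change 0.22, adjusted p = 8.67e-16 by limma's camera; adjusted p = 0.678 with an estimated correlation), although 0 of the 81 passed alone; Rplp1 and Rpl36 had the values 0.64 and 0.66. All 34 nuclear oxidative phosphorylation genes lay above 0 (median 0.21; adjusted p = 2.13e-08, and adjusted p = 0.678 with an estimated correlation), with 0 passing alone and Cycs at 0.43. Of 11 mitochondrial transcripts, 10 lay below 0 (median -0.29; adjusted p = 0.0271, and adjusted p = 0.843 with an estimated correlation), with 0 called and mt-Cytb at -0.33. In the same libraries the cluster of cells with the fewest UMIs held 28.6% of WT replicate 1 against 9.65% of WT replicate 2 and 6.51% and 13.6% of the KO replicates. The cytokine receptor and STAT list moved upward (adjusted p = 0.0271; adjusted p = 0.678 with an estimated correlation), with Il7r and Il18r1 called and 20 of 22 members not passing. The inhibitory receptor list moved upward (adjusted p = 0.0104; adjusted p = 0.678 with an estimated correlation) through Lag3, while 11 of 12 members did not pass: its median was 0.02 and its mean 0.51. The myeloid marker list moved downward (adjusted p = 0.0104; adjusted p = 0.678 with an estimated correlation) with Cd68 called, and 5 of 6 members did not pass. The mitochondrial call was lost without WT replicate 1 (adjusted p = 0.633), without KO replicate 1 (0.507), with the cycling clusters left out (0.0567) and, in a setting chosen after seeing the data, without the low-UMI cluster (0.186; 6.17e-05 to 0.843 over its alternatives). The inhibitory receptor call was lost without WT replicate 2 (0.35) and KO replicate 1 (0.0943). The cytokine receptor call was lost without WT replicate 2 (0.554), KO replicate 1 (0.0943) and KO replicate 2 (0.0688), and the myeloid call without KO replicate 1 (0.0943).

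Adjusted over the list alone, 3 members of the naive and stem-like list passed, all higher, against 0 over all genes. In the memory precursor list 4 were higher and 2 lower adjusted over the list alone, against 2 (Il7r, Il18r1) and 1 (Ly6c2) over all genes. In the terminal effector list the counts adjusted over the list alone were 3 higher and 3 lower, against 1 (Anxa1) and 2 (S1pr5, Zeb2). In the homing receptor list they were 4 higher and 2 lower, against 0 and 1 (S1pr5). Adjusted over the list alone, the inhibitory receptor list had 2 higher and the cytokine receptor list 3. The cytotoxic list and the apoptosis and survival list had 1 higher each, the X chromosome neighbours of Suv39h1 2 higher, and the myeloid and NK lists 2 lower each. The T cell receptor, S phase, G2 and M phase, heterochromatin, interferon, glycolysis, immediate early, heat shock, MHC class I and cholesterol lists, like the ribosomal, oxidative phosphorylation and mitochondrial lists, had 0 members passing either way. The median and the camera direction differed in sign in the interferon list (-0.03, mean 0.01, upward), the cholesterol list (-0.07, mean 0.05, upward) and the X chromosome neighbours (median under 0, mean 0.05, upward), as did median (0.01) and mean (-0.01) in the immediate early list, and none of these was called. B cell (2 tested genes), CD4 (3), red cell (4) and sex chromosome markers (4) were too few for a list test. None of them passed over all genes, while adjusted over the list alone 2 CD4 and 1 red cell marker were higher. By fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 0 lists passed (smallest adjusted p = 0.339, T cell receptor signalling), where 1 list had an unadjusted p under 0.05.

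**Figure D2:**
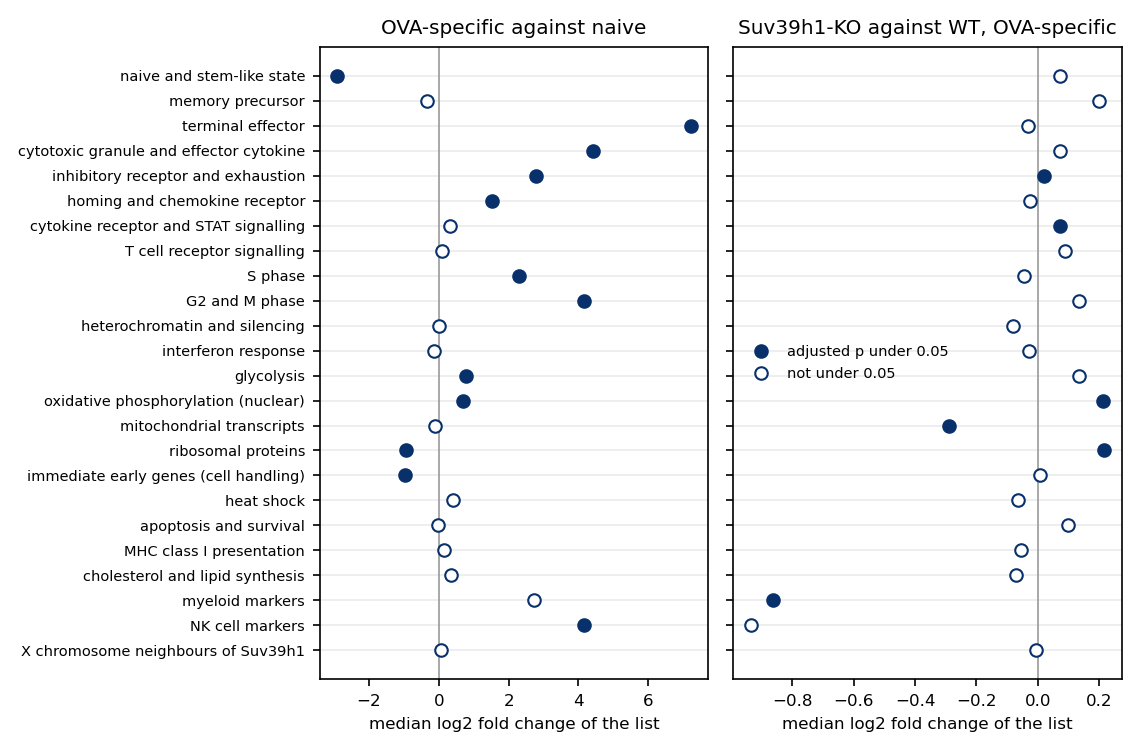
Median log2 fold change of each of the 24 lists tested in both comparisons (horizontal axes), OVA-specific against naive on the left and KO against WT in OVA-specific cells on the right; genes with 0 UMIs in a group enter at their lower bound. Filled points have a camera adjusted p under 0.05; the ribosomal protein list stood at -0.94 on the left and 0.22 on the right.

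The same genotype comparison was made within cycling cells, the only named class with 50 or more cells in each OVA-specific library. Of 7302 genes tested, 10 changed (5 higher and 5 lower in KO), and 7 of these were among the 31 called over all cells. Cycling cells are part of all cells, so the overlap is no separate test. Klra3, a lectin-like receptor of the Ly49 family, rose 5.19-fold (log2 fold change 2.38, SE 0.30, adjusted p = 0.00527) and Lag3 24.6-fold, while Bin1 rose 2.16-fold. AC168977.1 rose 50.1-fold; it stood at 50.2 and 12.3 CPM over all KO cells. Ly6c2 fell by 1.34, S1pr5 by 1.79 and Zeb2 by 1.08 on the log2 scale, and Lcn4, a lipocalin, fell by 3.04 (SE 0.39, adjusted p = 0.00527). Close relatives of Klra3 may share its reads, and over all cells Klra3 did not pass (log2 fold change 2.22, adjusted p = 0.598) but passed without KO replicate 1 (2.72, adjusted p = 1.53e-24) and without KO replicate 2 (1.67, adjusted p = 4.88e-09). With 1 library left out, Klra3 and S1pr5 kept their calls in cycling cells. Without WT replicate 2, Lag3 went from 4.62 to 7.46 (adjusted p = 0.0682) and AC168977.1 from 5.65 to 7.65 (0.105) on the log2 scale, and the calls of Ly6c2 (0.263), Bin1 (0.0962) and Lcn4 (0.131) ended. The calls of Ly6c2 (adjusted p = 0.612), Bin1 (0.0618) and Zeb2 (0.101) ended without WT replicate 1, and that of Lag3 without KO replicate 1 (0.104). DESeq2 called 3 of the 10 genes, and edgeR called 144 without KO replicate 1, 27 without KO replicate 2, 21 without WT replicate 2 and, in a setting chosen after seeing the data, 23 with the low-UMI cluster counted as cycling.

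Counted per cell at an equal depth of 2000 UMIs, Il7r was detected in 18.3% and 10.7% of KO cells against 4.4% and 5.30% of WT cells. Cxcr3, a chemokine receptor, was detected in 44.5% and 43.8% of KO against 31.6% and 32.4% of WT cells, and S1pr1 in 25.6% and 26.8% against 16% and 19.9%. Zeb2 was detected in 15.2% and 17.9% of KO against 34.4% and 27.7% of WT cells, and Cx3cr1 in 11.5% and 26.8% against 33.6% and 37.2%. Klrg1-negative Il7r-positive cells made up 14.6% and 5.36% of KO and 4.00% and 3.31% of WT cells. Negative means without a UMI at this depth, so a cell counted as negative may still hold the transcript. Klrg1-positive Il7r-positive cells made up 3.73% and 5.36% of KO and 0.40% and 1.99% of WT cells. Of 21 panel items, 9 had libraries that did not overlap between genotypes (6 higher and 3 lower in KO), where chance gives 33.3% for each, and 2 libraries against 2 allow no exact permutation p under 0.33. The count of 9 was 15 without WT replicate 2 and 16 without either KO replicate. Klf2, a zinc-finger factor of quiescent T cells and the third item lower in KO, overlapped before thinning (30.8% and 31.6% in WT, 28.6% and 32.3% in KO), so no order was read from it. Klrg1 overlapped at 43.2% and 50% of WT and 36.5% and 51.3% of KO cells. UMIs of Hbb-bs, a haemoglobin gene taken as a background of free RNA, were found in 3.20% and 2.46% of WT and 4.98% and 3.12% of KO cells. The Klrg1-positive Il7r-positive shares, the Klrg1-negative Il7r-positive shares in WT and in KO replicate 2 and the Il7r shares in WT lay near that level. Free Il7r RNA was not measured, so whether shares this low hold free RNA stays open, and no order was read from the 2 combined items. In naive cells Il7r was detected in 37.3% of WT and 40.7% of KO cells. Before thinning, Il7r was detected in 29.4% and 20.4% of KO and 6.47% and 8.92% of WT cells; thinning left out 152, 177, 83 and 55 shallower cells of WT replicates 1 and 2 and KO replicates 1 and 2.

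**Figure D3:**
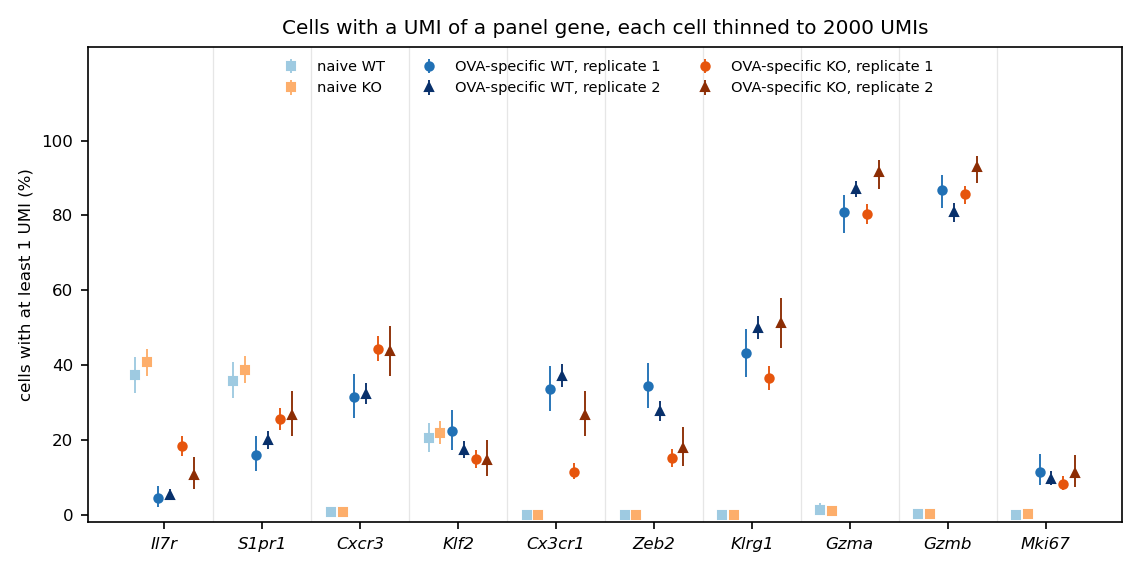
Percent of cells with at least 1 UMI of each gene in each of the 6 libraries after thinning every cell to 2000 UMIs; points are libraries and bars exact binomial 95% intervals for counting error. Il7r lay at 18.3% and 10.7% in OVA-specific KO against 4.4% and 5.30% in WT, and Zeb2 at 15.2% and 17.9% against 34.4% and 27.7%.

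No order of the genotypes was read from the share of cycling cells. Among named clusters whose leading genes were not themselves called, the cycling ones held 24.6% and 17.4% of WT and 18.4% and 22.9% of KO cells, a mean difference of -0.318 percentage points (exact permutation p = 1; no p under 0.33 was possible). In percentage points, the difference was 3.32 without WT replicate 1 and 1.95 without KO replicate 1, opposite in sign. With the third cycling cluster, which 1500009L16Rik helped define, 32.8% and 30.3% of WT and 31.7% and 33.0% of KO cells were in a cycling cluster. These counts leave out the low-UMI cluster, led by replication genes (Mcm3, Lig1, Cdc6). In it 7 of 11 cycling markers were raised, but it stayed unnamed under a depth limit set after seeing the data, since none of the 7 was among its 10 leading genes. Counted as cycling beside the clusters compared, it brought the shares to 53.2% and 27.0% of WT and 24.9% and 36.6% of KO cells, a difference of -9.38 percentage points (exact permutation p = 0.667). Under the stricter cell filter a cluster led by these genes was named cycling, and 42.4% and 32.4% of WT and 34.2% and 37.3% of KO cells were in cycling clusters, which overlapped. An unnamed cluster led by Ctla2a, Klra3 and Ccl5 held 38.0% and 41.9% of KO cells against 1.49% and 19.5% of WT cells. The exact permutation p for it was 0.333, the smallest possible. Klra3, which helped define this cluster, did not pass over all cells but was called within cycling cells, so no order was read from this share. Clusters led by Ctla2a and Serpina3g did not overlap either: 0% and 14.2% of WT against 29.5% and 38.2% of KO under the stricter cell filter, 13.6% and 20.1% against 37.9% and 24.3% with doublets kept and 0.746% and 9.65% against 23.6% and 21.5% at a Leiden resolution of 1.5. Called genes (Lilr4b with Anxa1 or Lag3) helped define the first and the last of these. At a resolution of 0.5, a larger cluster led by Ccl5, Ctla2a and Klre1 and named terminal-effector-like held 39.6% and 60.6% of WT and 61.5% and 52.7% of KO cells, which overlapped (exact permutation p = 0.667). At the resolution used elsewhere, a cluster led by Ctla2a and Eif3f held 18.9%, 14.5% and 16.8% of cells in 3 libraries but 0.358% of KO replicate 2 (exact permutation p = 0.667). The terminal-effector-like cluster held 18.2% and 25.4% of WT and 6.41% and 10.0% of KO cells, but S1pr5, Zeb2 and As3mt, themselves called, helped define it. Under the stricter cell filter 1 such cluster held 24.0% and 15.5% of WT against 4.86% and 0% of KO cells and a second 0% and 17.2% against 7.99% and 20.7%. With doublets kept the 2 held 24.8% and 21.5% against 9.33% and 0.357%, and 0.496% and 18.2% against 13.1% and 28.2%. No order was read from any of these, since called genes helped define them all. Interferon-response-like cells were at most 1.08% of any OVA-specific library, or 1.24% under the stricter cell filter.

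OVA-specific cells were compared with naive cells of the same genotypes to describe the response itself. Of 9168 genes tested, 4209 changed (2224 higher and 1985 lower in OVA-specific cells; edgeR with genotype in the model, 4 against 2 libraries). Cytotoxic and effector genes were among those that rose furthest. Gzmb, encoding granzyme B, stood at 1417.5 to 2757.7 CPM in the OVA-specific libraries against 0.559 and 0.431 CPM in the naive ones (adjusted p = 2.08e-11). Klrg1 was at least 483-fold higher, Gzmk, encoding granzyme K, at least 523-fold higher and the lectin receptor gene Klrc1 at least 464-fold higher, each against 0 naive UMIs and a floor of 3 UMIs over the group. Genes of naive cells were among those that fell furthest. Igfbp4, an insulin-like growth factor binding protein gene, went from 265 and 122 CPM to at most 0.196 CPM (log2 fold change -10.69, adjusted p = 1.31e-11), the gut homing receptor Ccr9 was 955-fold lower and the lymph node homing receptor Ccr7 177-fold lower.

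By list, all 20 terminal effector genes rose, including S100a4 (from 1.12 and 0.431 CPM to at least 1230.6 CPM), Anxa2 and the chemokine receptor Ccr2, with a median log2 fold change of at least 7.21 once genes without naive UMIs take their bound (adjusted p = 4.57e-64 by camera; adjusted p = 0.00856 with an estimated correlation). Of 19 cytotoxic genes 17 rose, among them Ccl4 (at least 200.1-fold) and Ifng (241-fold). Of 19 naive and stem-like genes 18 fell, among them Lef1 (9.05-fold), a factor of the naive program, and Il6ra (28.2-fold). Both calls held with an estimated correlation (adjusted p = 0.00944 for each). G2 and M phase genes (47 of 51 higher, such as Ccnb2 and Ube2c), S phase genes (37 of 42 higher, such as Tyms) and glycolysis genes (12 of 17 higher, such as Pfkp and Gapdh) rose by camera but had an adjusted p = 0.118 each with an estimated correlation. Nuclear oxidative phosphorylation genes rose (29 of 34 higher, Cox5b 2.93-fold; adjusted p = 0.697 with an estimated correlation). Ribosomal protein genes fell (69 of 81 lower, Rps29 3.90-fold; adjusted p = 0.501 with an estimated correlation). Inhibitory receptor genes rose (9 of 12 higher and 2 lower, with Pdcd1 at least 50.7-fold higher; adjusted p = 0.13 with an estimated correlation). So did homing receptors (13 higher and 6 lower of 21, with Cxcr3 47.2-fold higher; adjusted p = 0.194) and NK markers (4 of 5 higher, Klrb1c at least 17.7-fold; adjusted p = 0.501). Immediate early genes fell (14 of 22 lower, Fos 5.86-fold and Ppp1r15a 3.52-fold), with adjusted p = 0.233 by camera with an estimated correlation. These genes respond to the handling of cells and differed between the naive libraries (Junb at 1129.6 CPM in WT and 348 CPM in KO). Handling therefore cannot be told apart from infection in their fall. By fry, which does not compare a list with other genes, each list named in this paragraph passed (adjusted p = 0.000172 to 0.0181).

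In most of the lists that camera did not call, members moved both ways. By fry, some of them passed: memory precursor (adjusted p = 0.000665), apoptosis (0.0161), X chromosome neighbours (0.0231), heterochromatin (0.036), myeloid (0.04) and heat shock (0.04997). Memory precursor genes split into 5 higher, including Cxcr3 and Itga4, and 5 lower, including Bcl2 (11.9-fold) and Il7r (6.80-fold), with a median of -0.34 and a mean of 0.99. Cytokine receptor genes split into 11 higher (Il18rap 74.7-fold) and 9 lower (Il6st 20.6-fold), and interferon genes into 5 higher (Ly6a) and 7 lower (Iigp1, Oasl2). Of the heterochromatin list 8 rose, led by Hells, Uhrf1 (21.0-fold) and Ezh2 (6.01-fold), which also serve DNA replication or dividing cells, and 3 fell. The counts were 4 higher and 2 lower of 19 for T cell receptor signalling, 9 and 4 of 20 for apoptosis, 5 and 1 of 11 for heat shock, 3 and 2 of 13 for MHC class I, 4 and 0 of 16 for cholesterol and 1 and 2 of 11 for mitochondrial transcripts. The medians of the memory precursor list and of the apoptosis list (-0.03, mean 0.57) differ in sign from their camera direction, which is upward, and the CD4 marker list (3 higher, 2 lower) had a median of 3.61, or 3.21 at the bound, against a downward direction. Of the myeloid markers 4 rose and 1 fell of 7, of the B cell markers 2 rose and 1 fell of 5, of the X chromosome neighbours 4 rose and 2 fell of 18, of the red cell markers all 4 rose and of the sex chromosome genes 2 of 4 fell. Adjusted over the list alone the counts were the same for all but the cytokine receptor (12 and 10), oxidative phosphorylation (30 and 1), apoptosis (9 and 7), mitochondrial (1 and 1), cholesterol (1 and 0) and sex chromosome lists (0 and 3). Cx3cr1 lost its call without naive WT, without OVA-specific WT replicate 1 and without OVA-specific WT replicate 2 (edgeR adjusted p = 0.0712, 0.0509 and 0.0785, against 0.017 with all libraries and 2.31e-15 to 0.0785 over its alternatives).

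The naive KO and WT libraries, 1 of each, were compared without a test. Of 4229 genes with 50 or more UMIs in the higher library, 128 were at least 1.5-fold higher and 1003 at least 1.5-fold lower in KO by total UMIs; with TMM factors, which add 0.317 to every log2 ratio, the split was 379 higher and 509 lower. Jun, an immediate early transcription factor gene, was 10.1-fold lower in KO (95% interval 7.54 to 13.7), and Junb 3.24-fold lower (2.99 to 3.52), whereas Ndufb4, a respiratory chain subunit gene, was 5.80-fold higher (3.58 to 9.92). Other genes near the top were Gm11808 (5.09-fold, uncertain as a ribosomal protein pseudogene that may share reads), Phpt1, AY036118, Nme2, Gm26917, Grcc10, Rps27rt and Tomm6, and at the bottom Ppp1r35 (10.8-fold lower), Tomm20 (9.36-fold), Ndfip1, Adprhl2, Med30, Tbcc, Mri1, Gfer and 2210016F16Rik. Immediate early genes had a median KO to WT ratio of 0.713, at the 0.59th percentile of 10000 random lists matched on expression. Ribosomal protein (1.15) and oxidative phosphorylation genes (1.13) lay above all of the lists matched to them. On the log2 scale these 2 medians were 0.204 and 0.174, against -0.0799 and -0.0994 for the matched lists and -0.316 for all genes. The medians of the cholesterol list (2.40th percentile), the naive and stem-like list (4.54th) and the X chromosome neighbours (98.4th) are descriptions of these 2 libraries only. By total UMIs Il7r had a ratio of 1.03 (0.921 to 1.16), within counting error. With TMM factors, which add 0.317 to its log2 value, the interval lies above 1, so this reading turns with the scaling. Ltb, a lymphotoxin gene, was 2.71-fold lower by total UMIs (2.52 to 2.91).

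**Figure D4:**
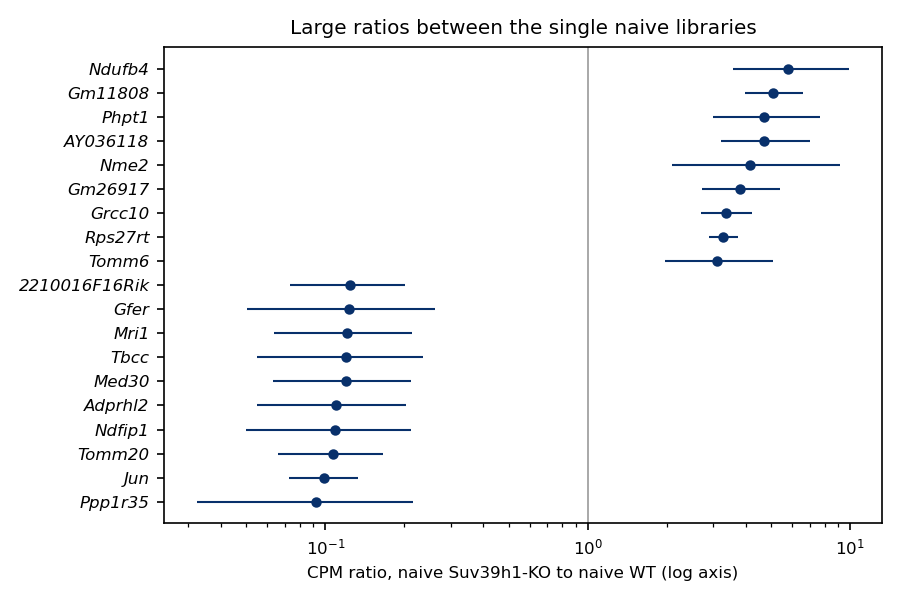
Ratio of CPM in the naive KO library to that in the naive WT library (log axis) for 19 genes with large ratios by the size rule; bars are exact conditional 95% intervals for counting error. Ndufb4 lay at 5.80 and Jun, 10.1-fold lower in KO, far below 1; with TMM factors every ratio lies higher by 0.317 on the log2 scale.

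Whether the genotype difference itself differed between naive and OVA-specific cells was tested with an interaction term over the 6 libraries, each naive library being assumed to vary like the OVA-specific ones. Of 9168 genes, 7 passed (1 above and 6 below 0). Ly6c2 went in opposite directions, from 141 CPM in naive WT to 336 CPM in naive KO and downward in OVA-specific cells (interaction -2.84 on the log2 scale, SE 0.23, adjusted p = 8.12e-05). Gm11808 (-2.60), Rpl27 (-1.61), encoding a ribosomal protein, Wdr89 (-1.59), Oaz1 (-1.35), the ornithine decarboxylase antizyme, and Snrpg (-1.28), a spliceosome core protein, were each higher in naive KO than in naive WT, and Adprhl2 (3.33) was 9.08-fold lower there. Gtf3a, Junb, E2f4 and Sqle, next upward, did not pass (adjusted p = 0.0906 to 0.193), but Junb passed without each of the 4 OVA-specific libraries (0.00257 to 0.0313) and with DESeq2 (0.00834). Without the low-count filter and without KO replicate 2 all 4 passed. The count of 7 was 26 without WT replicate 1, 13 without WT replicate 2, 20 without KO replicate 1 and 190 without KO replicate 2, where the split turned to 156 above and 34 below 0, and 3 with no cell filter, 36 with a stricter one, 19 with DESeq2 and 84 without the low-count filter. Of the 7 genes, 6, 5, 3 and 4 were still called without WT replicates 1 and 2 and KO replicates 1 and 2, and 3 with no cell filter. Rpl27, Oaz1 and Snrpg lost their calls without KO replicate 1 (adjusted p = 0.34, 0.33 and 0.322), without KO replicate 2 (0.0838, 0.133 and 0.124) and with no cell filter (0.0787, 0.099 and 0.116). Wdr89 lost its call with no cell filter (adjusted p = 0.0787) and without WT replicate 1 (0.0675), WT replicate 2 (0.0738) or KO replicate 1 (0.17), and Adprhl2 without WT replicate 2 (0.0549). Ly6c2 and Gm11808 kept theirs throughout. Of 17 genes called in OVA-specific cells with 20 or more UMIs in the naive pair, Suv39h1 aside, 15 had the same sign of KO to WT ratio in naive cells and 13 after the median ratio of all genes was taken off.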

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

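Of the tests in this part, those on passenger segments, on the X chromosome neighbours, on cell handling and on the ribosomal protein and oxidative phosphorylation genes as separate lists were chosen after the result they test was seen. After the values were seen, it was also asked that no neighbour pass adjusted over the list alone and that matched genes differ from members by at most 0.1 SD in each feature. Groups held at most 2 libraries, too few for a test of single outlying libraries.

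The genotype difference itself differed between naive and OVA-specific cells in 7 genes by the interaction test. The values were -2.84 on the log2 scale for Ly6c2, -2.60 for Gm11808, -1.61 for Rpl27, -1.59 for Wdr89, -1.35 for Oaz1, -1.28 for Snrpg and 3.33 for Adprhl2. Each rests on 1 naive library per genotype. A difference in handling or library making between the naive libraries therefore cannot be told apart from one of genotype in these values. Outside the values used in the comparisons, nearly every barcode had a second entry. It held a near copy of the first, with a median of 80.7% of detected genes shared in the library where that share was lowest. What the suffixes stand for is not given in the sources used here.

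The naive KO and WT libraries differed in 1131 genes by the size rule. Immediate early genes, which respond to the handling of cells, were low in KO, at the 0.59th percentile of matched lists. That value raised the question of handling before lysis and is therefore no test of it. The KO to WT ratio fell with transcript length across 7928 genes (Spearman -0.221 over genes, which are not independent replicates), and among genes of low, middle and high expression it was -0.0712, -0.166 and -0.376. A length-dependent difference in library making may therefore contribute. With 1 library per genotype, handling and an effect of Suv39h1 stay open beside it.

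For the genes called between KO and WT OVA-specific cells as a set, fewer cells of the terminal-effector-like cluster (18.2% and 25.4% of WT, 6.41% and 10.0% of KO) are argued against as the whole cause. Without that cluster the median change of 30 called genes was 0.951 of its value over all cells (0.742 to 1.07 over the genes). Called genes that helped define the cluster kept less: S1pr5 0.834, As3mt 0.857 and Zeb2 0.867 of their values. So did called genes not among its 10 leading genes, such as Fkbp10 (0.742), Tprgl (0.769), 1500009L16Rik (0.788) and Rap1b (0.831). The calls of As3mt and Zeb2 ended (edgeR adjusted p = 0.0507 and 0.0703). Those of 1500009L16Rik, Fkbp10, Chd3, Cirbp, Rap1b, Tesc, Tmem37, Tprgl, Vapa and Xpa ended as well (edgeR adjusted p = 0.0657 to 0.195). Other clusters may hold similar cells, so a smaller share of such cells was not excluded as a cause. Passenger segments of another strain may contribute, and the test left this open, since 8 of 28 called genes with a position had another called gene within 5 Mb, where random draws gave a median of 4 and an upper bound of 10. Within such pairs lay Chd3 and Cd68, Tprgl and Prkcz, Tesc and Ppp1cc, and Cirbp and 1500009L16Rik. DNA carried along around Suv39h1 may also contribute, since 2 of 19 X chromosome neighbours passed adjusted over the list alone, although 0 were called over all genes, their median absolute change lay at the 45.7th percentile of matched lists and none of the 28 lay on chromosome X. A response to the loss of Suv39h1 stays open beside these.

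The ribosomal protein and oxidative phosphorylation genes had a median log2 fold change of 0.22 (115 genes, 0.217 before rounding). Genes matched on length, GC content and expression had 0.171 (0.158 to 0.187 in the middle of the draws), but the members lay 0.311 SD above them in expression and 0.155 SD below in length. The lists taken apart had the same flaw: 0.217 against 0.174 with a gap of 0.368 SD in expression for the ribosomal protein genes, and 0.213 against 0.161 with a gap of 0.176 SD for the oxidative phosphorylation genes. These features were therefore not excluded, nor shown to be a cause. Without the low-UMI cluster the median was 0.166, or 0.767 of its value (0.74 to 0.837), which leaves open that such cells in WT replicate 1 may explain part of it. A difference between the genotypes stays open as well, and none of the 115 genes passed alone.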

How the results depend on the processing

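The alternatives that left out the low-UMI or the terminal-effector-like cluster, counted the former as cycling, or used the second suffix or both, were chosen after seeing the data. With 2 libraries per genotype, depth and number limit what can be called, and the cause of a moved count was not tested except where fewer or more genes or cells entered by construction. Of 554 comparisons of the 31 genes called between KO and WT OVA-specific cells with their alternatives, 482 kept the call, 72 kept the direction only and 0 reversed. The same counts were 2208, 71 and 0 for OVA-specific against naive cells, 75, 16 and 0 for the interaction and 50, 17 and 0 within cycling cells. The called lists gave 42, 23 and 0 between genotypes and 122, 10 and 0 against naive cells. These genes and lists were picked for being called, and most settings share most of their counts. Kept calls and directions are therefore no separate test. The count of 4209 genes stayed between 2820 and 4697.

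The count of 31 genes between genotypes was 185 without the low-count filter, 21 with DESeq2 (17 of them among the 31), 16 with equal cells and 20 without the terminal-effector-like cluster, and 36 to 301 with 1 library left out. The 7 interaction genes became 19 with DESeq2, 84 without the low-count filter, 3 without the cell filter, 36 with the stricter one, 14 with both suffixes, 23 without the low-UMI cluster and 13 to 190 with 1 OVA-specific library left out; without a naive library the term could not be estimated. The 10 genes in cycling cells became 3 with DESeq2, 23 with the low-UMI cluster counted as cycling and 10 to 144 with 1 library left out. The 6 called lists between genotypes became 0 with an estimated correlation and 0 by fry. The 12 against naive cells became 3 with an estimated correlation, while by fry each of the 12 passed (adjusted p = 0.000172 to 0.0181). Lists that camera did not call passed by fry too, from memory precursor to heat shock (adjusted p = 0.000665 to 0.04997). Fry does not compare a list with other genes.

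With the replicate number as a block, 129 genes were called between genotypes and 137 within cycling cells, and the cytokine receptor and STAT list had an adjusted p of 0.0575. Klra3, S1pr1 and Eomes were among the genes then called over all cells (edgeR adjusted p = 1.1e-05, 0.03 and 0.0458). The deviations of same-numbered libraries correlated at 0.226 over 4702 genes. The labels do not say that the number marks a shared animal, batch or day, so the block was not used elsewhere.

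In naive cells the 1131 genes became 2212 at 20 UMIs and 465 at 2-fold. The 9 panel items without overlap became 13 to 16 with 1 library left out, where fewer libraries make overlap rarer. The difference in cycling cells, -0.318 percentage points, ranged from -3.95 to 3.32 with 1 library left out, and turned sign at 3.32 (without WT replicate 1) and 1.95 (without KO replicate 1). It was -9.38 with the low-UMI cluster counted as cycling. The Klrg1 log2 fold change of -0.04 ranged from -0.29 to 0.20 with 1 library left out, with 0.12 without WT replicate 2 and 0.20 without KO replicate 1, and was 0.24 without the terminal-effector-like cluster. The Klrg1 share, -2.66 percentage points at equal depth, was 1.53 without thinning.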

Other observations

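The test in this part was set before its result was seen. Il7r, abundant in naive cells, was higher in OVA-specific KO than in WT libraries, which raised the hypothesis that KO cells lie closer to naive cells in general. It was tested with the 200 genes that fell most from naive to OVA-specific WT cells, of which 155 could be used, each WT replicate serving in turn for choosing the genes and for the comparison. Their median KO to WT ratio lay at the 57.9th percentile of 10000 lists matched on expression with 1 replicate and above all of the lists with the other. A general shift toward naive expression may therefore hold against 1 WT replicate only, and the test cannot tell.

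The naive-like cells fell into a pair of clusters that followed the libraries, 93.7% of naive WT and 2.15% of naive KO cells lying in the first and 5.34% and 96.9% in the second. UMIs of the haemoglobin gene Hbb-bs, which T cells should lack, were found in 3.20% and 2.46% of OVA-specific WT and 4.98% and 3.12% of OVA-specific KO cells at 2000 UMIs. The free RNA of other genes was not measured, so whether their shares at this level hold free RNA stays open.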
